A study of Nasonia vitripennis with 39 samples.

How the data were processed

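RNA was measured by poly(A)-selected sequencing in heads and abdomens of the parasitoid wasp Nasonia vitripennis, taken 1 day after emergence. All animals came from the Whiting Polyploid Line, a spontaneously arisen laboratory line in which males carry 1 or 2 chromosome sets (1N, 2N) and females carry 2 or 3 (2N, 3N). In this haplodiploid species males usually develop from unfertilised eggs and are 1N, and females are usually 2N. The 39 libraries form 8 groups by ploidy, sex and tissue, with 5 libraries each except the 2N female abdomens, which have 4. Groups were read from the labels. The labels do not say which head and abdomen came from the same animal, nor whether a library is 1 animal or a pool, so p-values measure the spread between these libraries only. Libraries are named below by their group and library number.

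Per the labels' protocols, RNA was extracted with an insect tissue kit without DNase treatment, poor samples were discarded by absorbance ratios, and libraries were made with a poly-T bead purification and an NEBNext Ultra kit. The labels give no strand setting, so reads of overlapping and antisense genes were not told apart here. The submitters' processing notes name STAR 2.7.11a and RSEM 1.3.1 without a role or order. The genome build and annotation behind the deposited tables are not given in the sources used here. All 14621 gene identifiers matched the symbols of the NCBI RefSeq table of assembly Nvit_psr_1.1, which was used only for names and synonyms, so no coordinates are given.

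The authors deposited a table of estimated counts for 14621 genes, not normalized, in which 16.8% of the values above or at 0 are not whole numbers. These estimated counts were rounded to whole numbers, which changed no value by more than 0.5. The authors also deposited a TPM table for 14613 genes (TPM, scaled for gene length and library total), which was used only for alternatives. An estimated count divides reads that match several genes among them, so members of gene families with near-identical copies (cytochrome P450, serine proteases, odorant receptors, defensins) carry that uncertainty. No gene-level value tells splice forms apart. The tables hold no row without a gene and no column of another sample.

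Library totals ran from 16.3 to 132 M estimated counts. They fell into 20 shallow libraries of 16.3 to 25.1 M and 19 deep libraries of at least 32.9 M, with none between, and the border was set at 30 M. These classes are uneven over the groups. Deep libraries make up 1 of 5 of the 1N male heads, 4 of 5 of the 2N male heads, 0 of 5 of the 2N female heads, 3 of 5 of the 3N female heads, 4 of 5 of the 1N male abdomens, 5 of 5 of the 2N male abdomens, 1 of 4 of the 2N female abdomens and 1 of 5 of the 3N female abdomens. The 14 libraries whose names end in a letter are all shallow. Depth class was treated as a possible library batch, although the labels name none. No pair of libraries within a group agreed within sampling noise (smallest chi-square per degree of freedom 10.8 over 76 pairs). Intervals from counts cover counting error only.

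Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with TMM normalization and the filterByExpr filter, two-sided, with Benjamini-Hochberg adjustment over all genes tested in a comparison. A gene is said to have changed, risen or fallen where the adjusted p was under 0.05. Heads were fitted together (10846 genes), as were abdomens (11884 genes), and all 39 libraries (12402 genes) for tissue and for ploidy by tissue. There were 16 comparisons: ploidy within each sex and tissue, sex at equal ploidy and at the usual ploidy, tissue within each kind of animal, and the differences of the ploidy effect between tissues and between sexes. These designs were fixed before the data were examined. Levels are CPM (counts scaled by the TMM library size) as mean ± SD; those in the tissue comparisons come from the fit of all libraries and differ slightly from those of the single-tissue fits. Log2 fold changes carry the standard error of the fit. Where a group has no count, the fold is a lower bound from 3 counts over the group, and where it has 1 to 3 counts the ratio is given with its 95% counting interval.

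The genes named were chosen by a rule fixed in advance, with a symbol in place of the planned description and with the exceptions given below. Not every gene that the rule selects is printed. Among changed genes with a mean of at least 5 CPM in the higher group and no overlap between the groups, it takes the 10 largest rises and the 10 largest falls with an informative name. From each gene list it takes up to 2 members that rose and 2 that fell by smallest adjusted p. It adds the sex determination genes, the DNA methyltransferase and, of genes without a descriptive symbol, at most 2 in each direction by smallest adjusted p. Vitellogenin was part of that rule, but no symbol in the tables names it, so it is not analysed here. The text shows a selection of these genes. Oskar and nanos were always added as well, which the planned rule did not provide for. The rule was not applied to the differences of the ploidy effect between tissues and between sexes. The genes printed there are genes also named for ploidy in female abdomens.

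The 33 gene lists planned before the data were examined matched descriptions, which the tables do not carry, and 94.3% of the identifiers are numbered loci. They were redrawn as 22 lists by symbol after the identifiers had been read and before any test was run, so most lists hold only the named members of a family. Lists with at least 3 tested members (20 in every comparison) were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry (directional and mixed) were run beside it.

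The alternatives fixed in advance were DESeq2 size factors in the same test, no low-count filter, the DESeq2 1.42.0 Wald test, voom with sample weights, limma-trend on log2(TPM + 1) with and without a filter at 1 TPM and on log2(TPM + 0.1), a test against a fold of 1.5, only the groups compared, all 39 libraries in 1 fit, a term for library names that end in a letter, and leaving out each library in turn. Added after the data were seen were a term for deep libraries, deep or shallow libraries alone where at least 2 per group remained, library totals without TMM, leaving out the 2 libraries per tissue that correlate least with their group, and, for female abdomens, a term for the germline list. The term for deep libraries was chosen from the totals, before any test.

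The edgeR test of each comparison was run on simulated counts drawn from the real means and library sizes. In these, 67, 67 and 66 genes were changed 1.5, 2 and 4-fold. DESeq2, voom, limma-trend on log2 CPM, camera and fry were run on simulated counts only for ploidy in female heads and female abdomens. The added terms, the splits of libraries, the leaving out of libraries and the tests of explanations were not run on simulated counts. For ploidy in male heads edgeR recovered 17.9%, 59.7% and 87.9% of genes changed 1.5, 2 and 4-fold, with 14 false among 124 calls. For ploidy in female heads the shares were 23.9%, 56.7% and 87.9%, for male abdomens 13.4%, 37.3% and 74.2%, and for female abdomens 1.49%, 32.8% and 48.5%. Recovery for ploidy by sex was 4.48%, 26.9% and 71.2% in heads and 0%, 8.96% and 53% in abdomens. Over all 16 comparisons recovery of 4-fold changes ran from 48.5% to 87.9%. In simulated female heads and female abdomens, the changed list ranked first among 21 lists and 0 random lists were called. The simulated genes were drawn independently of one another, so this does not test the calls of lists whose members are correlated.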

Results

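The series profiled heads and abdomens of 1N and 2N males and of 2N and 3N females of the Whiting Polyploid Line of Nasonia vitripennis, to describe expression across ploidy, sex and tissue. There were 5 libraries per group, and 4 for the 2N female abdomens. Library totals were 16.3 to 41.8 M estimated counts in 1N male heads, 18.8 to 101 M in 4 of the 2N male heads with 132029645 counts in the other, B11, 16.7 to 18.7 M in 2N female heads and 18.1 to 71.9 M in 3N female heads. In abdomens they were 18.2 to 66.2 M in 1N males, 35.7 to 124 M in 2N males, 19.9 to 45.04 M in 2N females and 17.3 to 79.3 M in 3N females. Libraries over 30 M are called deep here and the others shallow. The median correlation of a library with the others of its group was lowest in the 1N male abdomen B6A (0.893), the 3N female abdomen B39A (0.915), the 1N male head B5D (0.937) and the 2N female head B21 (0.968).

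The first principal component carried 48.1% of the variance and set female abdomens apart from all other groups, and the second, with 33.8%, set male abdomens apart from heads. On the first component the 3N female abdomens were spread more widely than any other group.

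**Figure D1:**
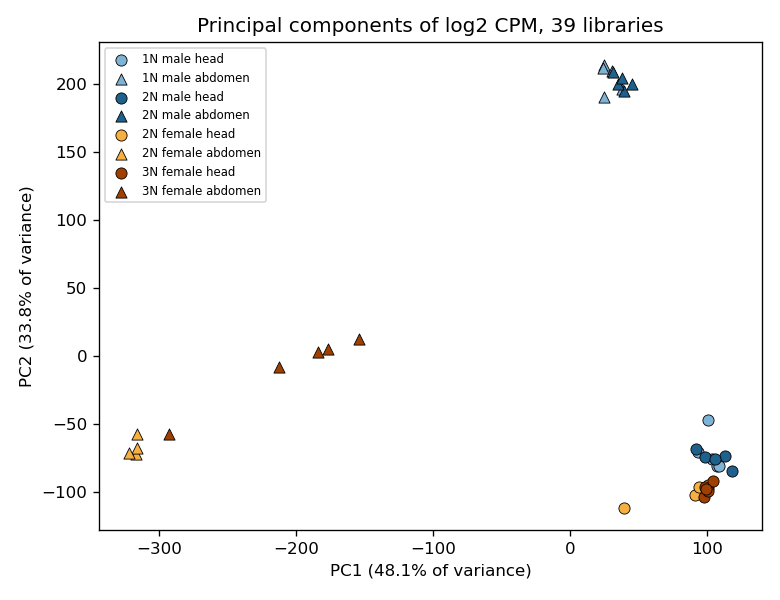
First and second principal components of log2 CPM for the 39 libraries, coloured by ploidy and sex, with circles for heads and triangles for abdomens. The 4 libraries of 2N female abdomens lie between -321.8 and -316.0 on the first component, the 5 of 3N female abdomens between -292.5 and -153.8, and all heads and male abdomens at or above 23.9.

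By the main test few genes passed the threshold for ploidy in heads and in male abdomens, many passed for ploidy in female abdomens, and most passed for sex in abdomens and for tissue. The small counts depended on the fit. Under the alternatives they ran from 0 to 1036 in male heads, 0 to 1999 in female heads and 0 to 71 in male abdomens. The number of genes past the threshold was 8 in male heads, 34 in female heads, 5 in male abdomens and 4605 in female abdomens for ploidy. Sex gave 3025 and 2346 genes in heads, at equal and usual ploidy, and 9919 and 9938 in abdomens. Tissue gave 8079 genes in 1N males, 8096 in 2N males, 9961 in 2N females and 9034 in 3N females.

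**Figure D2:**
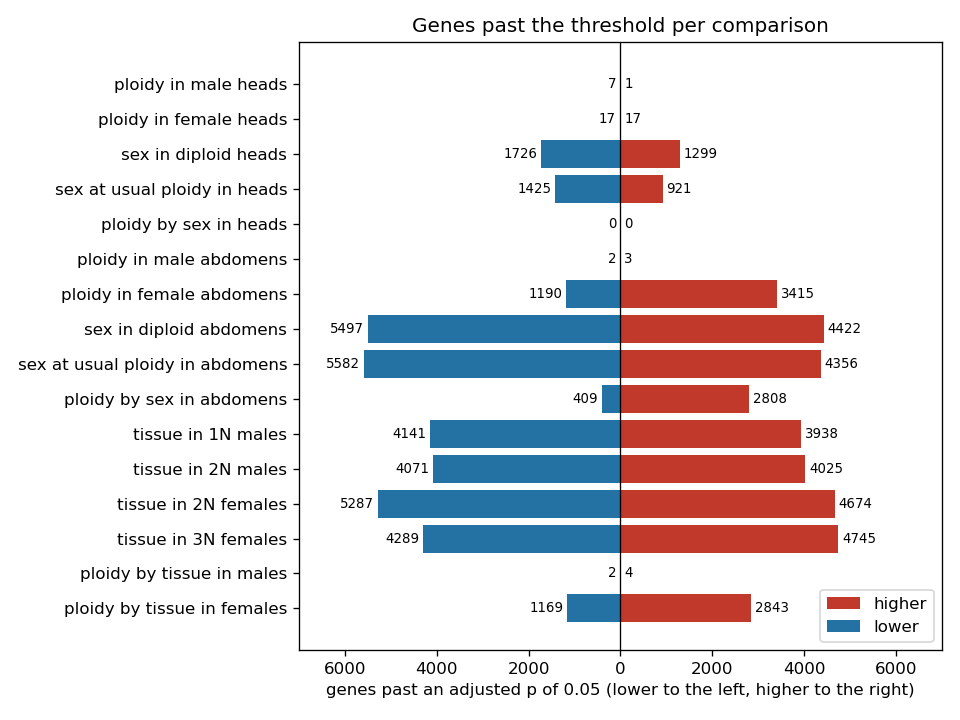
Number of genes with an adjusted p under 0.05 in each of the 16 comparisons, with higher genes to the right and lower genes to the left on a linear axis. For ploidy, 3415 genes were higher and 1190 lower in 3N than in 2N female abdomens, and 3 were higher and 2 lower in 2N than in 1N male abdomens.

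Ploidy in male heads was compared as 2N minus 1N. The defensin LOC100121630 (synonym Def2-3), an antimicrobial peptide of the innate immune response, was lower in 2N heads, at 8.45 ± 2.69 CPM against 29.6 ± 12.5 CPM (SD, n = 5 each; log2 fold change -1.82 ± 0.25 SE, adjusted p = 0.00331). The uncharacterised LOC116418369 fell from 5.29 ± 2.40 to 0.709 ± 0.394 CPM (log2 -2.81, adjusted p = 0.00331), and LOC107981377 rose from 1.25 ± 0.324 to 3.53 ± 1.04 CPM (log2 1.49, adjusted p = 0.0307). The call of LOC107981377 was lost without B1A (adjusted p = 0.0586), B2A (0.066), B4A (0.0968), B11 (0.0812), B13 (0.0833) or B14 (0.0551). These belong to 8 genes past the threshold, 1 higher and 7 lower, while 1159 of 10846 genes had an unadjusted p under 0.05.

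As groups in male heads, the immune list (8 tested, 1 fell, median log2 -0.39) and the cuticle list (27 tested, 0 past the threshold over all genes, median log2 -0.52) lay lower than other genes by camera (adjusted p = 0.000694 for each). Among list members alone, that is adjusted over the list alone, 2 immune and 4 cuticle genes fell. The adjusted p with an estimated correlation was 0.102 for the immune list and 0.478 for the cuticle list. Transformer (Tra), doublesex (Dsx) and fruitless (Fru), the sex determination genes of insects, did not pass the test (log2 -0.45, -0.13 and 0.35; adjusted p = 0.43, 0.802 and 0.588), nor did the maintenance DNA methyltransferase Dnmt1a (log2 0.03, adjusted p = 0.967).

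Of the 1N male heads 1 of 5 is deep and of the 2N heads 4 of 5, so too few libraries remained for a test within a depth class, and with a term for deep libraries 0 genes passed edgeR's test, as with a term for letter-named libraries and with male heads alone. The count was 75 with DESeq2 and 1036 with voom, and leaving out single libraries gave 3 (without B1A, B2A, B11 or B14), 4 (without B4A or B15), 5 (without B13), 19 (without B5D) and 63 genes (without B3); without B12A 11 genes were lower.

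Ploidy in female heads was compared as 3N minus 2N. The segmentation and neurogenesis repressor hairy rose from 4.92 ± 1.21 to 14.4 ± 2.24 CPM (n = 5 each; log2 1.55 ± 0.31, adjusted p = 0.042), and the zinc finger gene Krüppel (Kr) from 5.45 ± 0.898 to 13.2 ± 3.07 CPM (log2 1.27 ± 0.25, adjusted p = 0.0393). LOC100121630 was lower here too, at 18.8 ± 2.73 CPM in 3N against 48.1 ± 7.77 CPM in 2N heads (log2 -1.36 ± 0.25, adjusted p = 0.0306). Among genes without a descriptive symbol, LOC100114125 (log2 1.34) and LOC103317497 (log2 2.75) rose, and LOC100120541 (log2 -1.01) and LOC100121344 (log2 -0.70) fell. LOC100114125 and LOC100120541 kept their calls without any 1 library. The call of hairy was lost without any 1 of the 10 libraries (adjusted p from 0.0577 without B33 to 0.108 without B21), that of Kr without any except B33 (0.0646 without B35A to 0.0975 without B21) and that of LOC100121630 without any except B35A (0.0527 without B34A to 0.0937 without B23). LOC103317497 lost its call without B22, B23, B24, B25, B31 or B32 (0.0519 to 0.0584) and LOC100121344 without B23, B25, B31 or B32 (0.0509 to 0.0739). In all 17 genes rose and 17 fell, and 1988 of 10846 had an unadjusted p under 0.05. Of all genes tested, 1575 had no overlap between the groups, against 129 for ploidy in male heads.

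Channels and receptors of neurons lay higher in 3N heads as a group (20 tested, median log2 0.53, camera adjusted p = 0.000319). Oxidative phosphorylation (63 tested, median log2 -0.21, adjusted p = 2.8e-07), cuticle (27 tested, median -0.60, 0.00484), immune (8 tested, median -0.58, 0.0139), mitochondrial ribosomal proteins (4 tested, median -0.27, 0.0326) and the yellow and royal jelly family (14 tested, median -0.33, 0.037) lay lower. Over all genes only LOC100121630 among their members passed the threshold. Adjusted over the list alone, 8 neuronal genes and 1 cuticle gene rose, and 3 immune, 2 cuticle and 2 mitochondrial ribosomal genes fell. The adjusted p with an estimated correlation was 0.383 for these lists except oxidative phosphorylation, where it was 0.486. Tra, Dsx, Fru and Dnmt1a did not pass the test (log2 -0.09, 0.25, 0.58 and 0.15; adjusted p = 0.827, 0.428, 0.169 and 0.655). The posterior determinant oskar had a log2 difference of -2.25 (adjusted p = 0.0671), with 29.4 ± 40.4 CPM in the 2N heads because of B21, at 101.5 CPM.

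All 2N female heads are shallow and 3 of 5 3N heads deep; among shallow libraries alone, 5 against 2, 1913 genes passed (1353 higher, 560 lower), 29 of them among the 34, and with a term for deep libraries 623 passed. The count was 72 (26 higher, 46 lower) with library totals alone, 154 with the letter term, 562 with DESeq2, 1999 with voom, 1805 with female heads alone, 74 with all libraries in the fit, 22 without the count filter and 0 against a fold of 1.5. Leaving out single libraries gave 2 (without B23, B25, B31 or B32), 3 (B24), 5 (B22), 7 (B21), 9 (B34A) and 17 genes (B33, 3 of them lower), and without B35A 10 genes were higher.

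Whether the ploidy difference in heads depended on sex was tested directly. By edgeR 0 of 10846 genes passed, with 1044 at an unadjusted p under 0.05 and a smallest adjusted p of 0.308. DESeq2 gave 13, voom 622, log2(TPM + 1) without a filter 3, the fit with a letter term 1 and the fit without B3 1. Oxidative phosphorylation differed as a list (median log2 -0.21, camera adjusted p = 3.52e-06), as did the hexamerins, storage proteins of the fat body (median log2 1.46, 0.0282), with adjusted p = 0.92 and 0.516 with an estimated correlation.

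For ploidy in male abdomens, 2N minus 1N, 5 genes passed, all without a descriptive symbol. LOC100120653 rose from 82.5 ± 9.54 to 148 ± 20.6 CPM (n = 5 each; log2 0.85 ± 0.13, adjusted p = 0.0144) and LOC100115271 fell from 24.7 ± 2.11 to 15.7 ± 1.10 CPM (log2 -0.65 ± 0.11, adjusted p = 0.0335). LOC100115513 was at least 28.9-fold higher (163 counts against 0, adjusted p = 0.00706), and LOC103316021 at least 26.4-fold lower (0 counts against 42, adjusted p = 0.00706). LOC100107367 had 290 counts against 3, a ratio of 51.3 (95% counting interval 17.4 to 250, adjusted p = 0.00706), with the 3 counts in B9 alone. Leaving out B7 or B10 ended the call of LOC100120653 (adjusted p = 0.0569 and 0.0544), and that of LOC100115271 was lost without B7, B10, B16, B17, B19 or B20 (0.0672 to 0.101). The last of the rises, LOC100120653, exceeds the number the naming rule allows and was named because the list is so short, after its values were seen.

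In male abdomens 645 of 11884 genes had an unadjusted p under 0.05, and 0 of 20 gene lists passed camera (smallest adjusted p = 0.3, oxidative phosphorylation; 0 also with an estimated correlation and by fry). Tra, Dsx, Fru and Dnmt1a had log2 differences of -0.07, -0.05, 0.03 and -0.07 (adjusted p = 1 for each). Among deep libraries alone, 4 against 5, 17 genes passed and 1 of them was among the 5. The count was 71 with DESeq2, 18 with voom, 30 with all libraries in the fit, 10 without B6A and B39A, 9 without B6A, 8 without B8 or without B20, 3 against a fold of 1.5, 1 on either log2 TPM scale with the filter, and 0 with male abdomens alone. The 2 lower genes became 1 without B19, 4 without B8 or B9 and 5 without B6A or B20.

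Ploidy in female abdomens was compared as 3N minus 2N. Of 42 cytochrome P450 enzymes, which oxidise lipids, hormones and foreign compounds, 33 rose and 0 fell, with a median log2 fold change of 4.89. CYP4AB8 rose from 0.781 ± 0.344 to 28.2 ± 14.7 CPM (n = 4 and 5; log2 5.19 ± 0.55, adjusted p = 1.19e-05) and CYP4AB18 from 0.170 ± 0.147 to 35.8 ± 22.9 CPM (log2 7.82 ± 1.55, adjusted p = 0.000621). Cuticle proteins rose in 17 of 30, among them CPR19, from 8.21 ± 5.80 to 786 ± 575 CPM (log2 6.58, adjusted p = 1.53e-05), CPR18 (log2 7.31, and 8.32 without B26A) and CPR34 (log2 6.92, and 7.51 without B26A). Of 14 cell cycle genes 7 fell and 1 rose (median log2 -0.59).

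Members of other lists rose as well in 3N female abdomens. Serine proteases and their homologues rose in 21 of 39 (median log2 3.28; SP67 5.44), glutathione transferases and carboxylesterases in 16 of 29 (median 1.77; CCE-A8 6.81, and 7.62 without B26A), the yellow and royal jelly family in 10 of 15 (median 3.66; Mrjpl7 4.49) and neuronal receptors and channels in 12 of 19 (median 3.62), with the ligand-gated channels pHCl (log2 4.94) and GRD (log2 3.77). Subunits of the respiratory complexes rose in 26 of 65 (median 0.44), for instance succinate dehydrogenase B, SdhB, from 49.8 ± 12.9 to 110 ± 44.9 CPM (log2 1.14, adjusted p = 0.00188). Of 8 immune genes 4 rose, including the defensin Def1-2 (log2 6.07) and the prophenoloxidase ppo1 (log2 5.24). The adipokinetic hormone receptor Akhr, which releases stored lipid from the fat body, rose from 0.486 ± 0.267 to 25.7 ± 20.1 CPM (log2 5.75), and the ecdysone receptor Ecr by log2 1.07. Of 3 muscle genes, Zasp66 (log2 4.08) and the tropomyosin Tm1 (log2 1.59) rose and Tm2 fell (log2 -0.42, adjusted p = 0.00244), and 2 of 3 hexamerins rose.

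Among genes that fell in 3N female abdomens were the centromeric histone Cenp-a (log2 -0.90), the mitotic regulator Bora (-0.88), the mitotic kinase Cdk1, from 428 ± 29.7 to 234 ± 70.7 CPM (-0.87, adjusted p = 0.0494), and the cohesin subunit Smc1a (-0.65); the transcription factor E2f8 rose (1.02). DNA replication and repair genes fell in 4 of 15, with the polymerase Pol-iota at log2 -0.54, and both DNA methylation genes fell, Mbd (-0.67) and Dnmt1a (-0.51, adjusted p = 0.0141). The germline determinants oskar (652 ± 178 against 941 ± 68.3 CPM, log2 -0.53, adjusted p = 0.336) and nanos (log2 -0.76, adjusted p = 0.281) did not pass the test. The call of Cdk1 was lost without any 1 library except B39A (adjusted p = 0.0777 to 0.119), that of Bora without B27, B28A, B30, B36A or B38 (0.0519 to 0.0838), and that of Dnmt1a without B27 (0.0862) or B36A (0.0505). Of 11 cilia and dynein genes 1 fell. The uncharacterised LOC100115486 (log2 7.92) and LOC100120906 (log2 5.49) rose, while LOC100117027 (log2 -5.42) and LOC100678734 (log2 -0.61) fell.

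The sex determination genes Dsx and Tra, which carry sex-specific splice forms in insects, were higher in 3N than in 2N female abdomens. Dsx was at 249 ± 169 CPM in 3N and 9.53 ± 1.56 CPM in 2N abdomens (log2 4.70 ± 0.57, adjusted p = 1.38e-05), and Tra at 99.4 ± 59.5 against 30.6 ± 2.77 CPM (log2 1.70 ± 0.34, adjusted p = 0.00069). Fru did not pass the test (log2 0.22, adjusted p = 0.487). Dsx was also over 16-fold lower in 2N female abdomens than in male abdomens and 2N female heads. It thus belongs to the 1771 genes of that kind examined below, whose median log2 fold change in 3N female abdomens was 4.61. For these genes a lower share of ovary RNA in the 3N abdomens stays open.

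**Figure D3:**
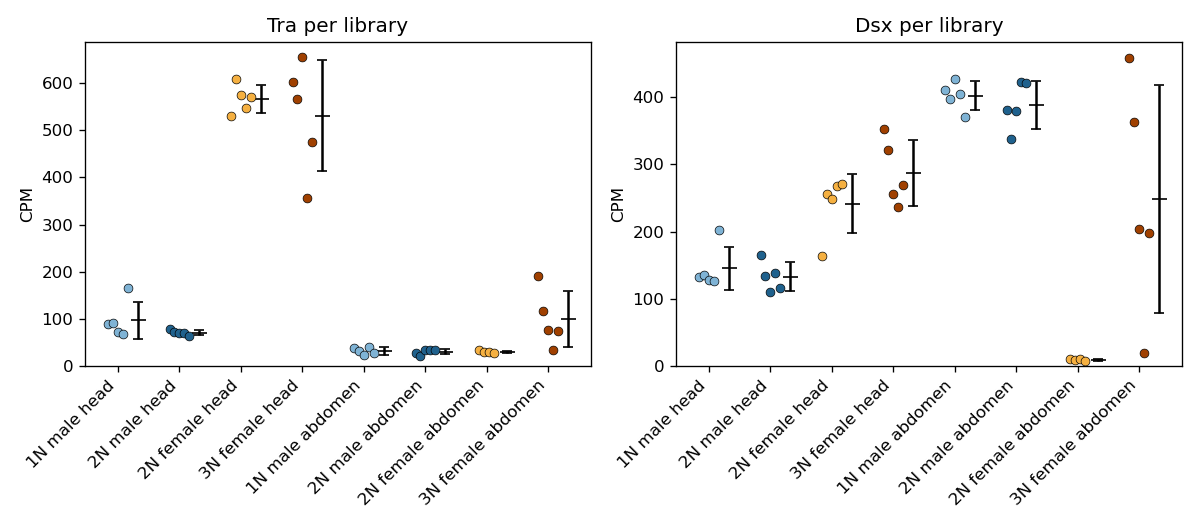
Expression of Tra (left) and Dsx (right) in CPM on linear axes, with a point per library, coloured by ploidy and sex, and the mean ± SD of each group beside the points. Tra lies between 356.3 and 654.4 CPM in female heads and between 64.35 and 164.8 CPM in male heads; Dsx lies between 7.453 and 10.81 CPM in 2N female abdomens and between 19.52 and 458.4 CPM in 3N female abdomens.

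By camera 10 of 20 lists passed in female abdomens: cytochrome P450 (adjusted p = 1.72e-08), cuticle (0.00108), yellow and royal jelly family (0.00311), neuronal, oxidative phosphorylation and the transferases and carboxylesterases (0.00352 each) and serine proteases (0.00591) upward, and cell cycle, DNA replication and repair (0.00352 each) and cilia and dynein (0.0344) downward. With an estimated correlation 0 passed (adjusted p = 0.346 for P450, cuticle, the yellow family, cell cycle, DNA repair and cilia, 0.393 neuronal, 0.453 transferases, 0.49 proteases and 0.618 oxidative phosphorylation). Adjusted over the list alone, 34 P450, 18 cuticle, 21 protease, 16 transferase, 10 yellow family, 12 neuronal and 30 oxidative phosphorylation genes rose, and 8 cell cycle and 2 DNA repair genes fell. Odorant receptors (2 of 48 rose; on the log2(TPM + 1) scale 1 rose and 3 fell) and gustatory receptors (3 of 13 rose), ribosomal proteins (1 of 4 cytosolic and 0 of 4 mitochondrial) and germline genes (1 of 5 fell) did not pass camera (adjusted p = 0.804, 0.985, 0.737, 0.21 and 0.128). Nor did the immune (adjusted p = 0.201), muscle (0.506), hexamerin (0.21), sex determination (0.132) and hormone lists (0.139).

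The 3N libraries differed from one another in the same groups. In B39A the P450 list had a median of 0.66 (log2) above the mean of the 2N abdomens, while in the other 4 libraries it lay between 4.08 and 5.28. The cuticle list lay at 0.85 in B39A and between 2.25 and 4.05 in the others, and the cell cycle list at -0.13 and between -0.88 and -0.65.

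**Figure D4:**
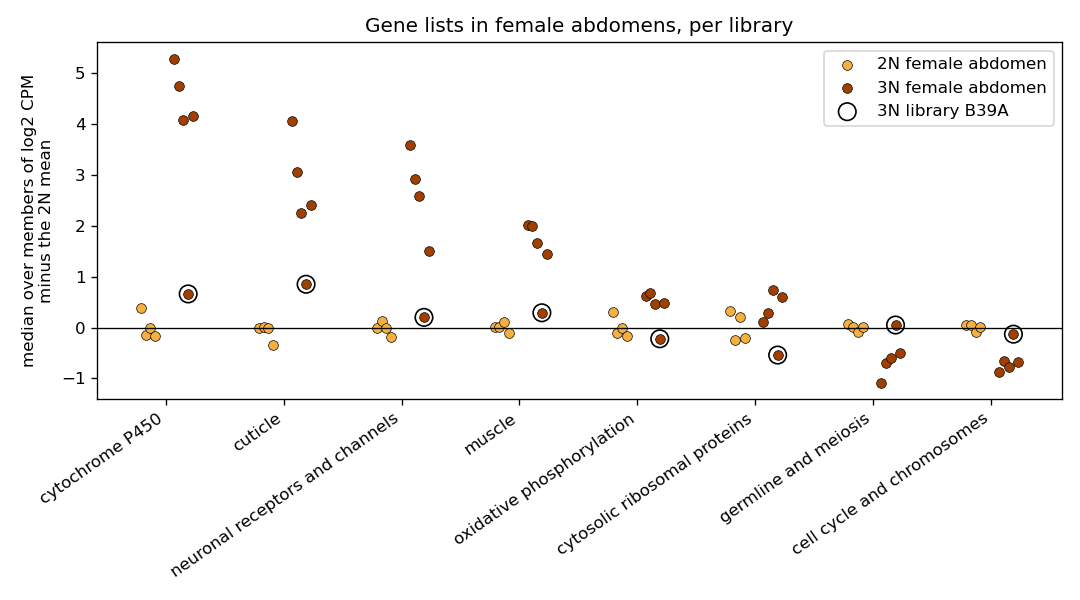
Median over the members of 8 gene lists of log2 CPM minus the mean of the 2N abdomens, with a point per female abdomen library and B39A ringed. The P450 median lies at 0.66 in B39A and between 4.08 and 5.28 in the other 3N libraries.

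In total 3415 genes rose and 1190 fell in 3N female abdomens, 2967 and 15 of them over 2-fold; on the log2(TPM + 1) scale 2298 rose and 2929 fell. Among shallow libraries alone, 3 against 4, 2249 genes passed (1814 higher, 435 lower), 2065 of them shared, against 7588 with voom, 2723 against a fold of 1.5, and 6470 without B6A and B39A. The lower count fell without any 1 library except B39A. It was 378 without B27, 561 without B36A, 609 without B28A and 724 without B26A or B38. It was 728 without B30, 750 without B37A and 898 without B40A, against 1589 without B39A.

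The ploidy difference in female abdomens differed from that in male abdomens for 3217 of 11884 genes (2808 higher and 409 lower in females; 1324 and 1300 on the log2(TPM + 1) scale). Dsx (difference of log2 fold changes 4.75 ± 0.69, adjusted p = 0.000153), Tra (1.77 ± 0.45, 0.00688), CPR18 (7.39 ± 1.06, 0.000148) and Akhr (5.69 ± 0.90, 0.000218) rose more in females. So did 30 of 42 P450 enzymes, 17 of 30 cuticle genes and 11 of 19 neuronal genes, while 1 other cuticle gene passed in the other direction. These lists passed camera (adjusted p = 9e-08, 0.0019 and 0.0213), as did cell cycle genes downward (2 of 14 passed alone, median log2 -0.63, 0.00183), though not with an estimated correlation (adjusted p = 0.445, 0.445, 0.514 and 0.246). The steps compared are 2 to 3 and 1 to 2 chromosome sets, and the count was 5422 with voom and 5021 without B6A and B39A. The lower count was 164 without B27, 215 without B36A, 239 without B28A, 250 without B37A or B38, 260 without B30 and 954 without B39A.

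The ploidy difference in females also differed between abdomen and head, for 4012 of 12402 genes (2843 more positive in abdomens, 1169 more negative). Dsx (4.25 ± 0.51, adjusted p = 8.67e-08), Tra (1.60 ± 0.37, 0.00112), CYP4AB18 (9.47 ± 1.57, 1.28e-05) and CPR18 (7.92 ± 0.82, 1.79e-08) rose more in abdomens. Dnmt1a moved the other way (-0.79 ± 0.25, 0.0128). P450 enzymes were more positive in 30 of 42 and cuticle genes in 15 of 34 (camera adjusted p = 8.06e-11 and 4.84e-06, and 0.267 and 0.209 with an estimated correlation). The split was 3094 to 457 with library totals alone, which shifted the median of all genes by 0.173, and 1699 to 1485 on the log2(TPM + 1) scale. The count was 2073 among shallow libraries, 2409 against a fold of 1.5, 6613 with voom and 6478 without the libraries that correlate least with their group. Without B39A alone 3035 were more positive and 2619 more negative, and the negative count was 757 without B36A and 772 without B37A.

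In males 6 of 12402 genes differed in their ploidy difference between abdomen and head, 4 more positive and 2 more negative in abdomens, with 805 at an unadjusted p under 0.05. The cuticle list was more positive in abdomens (34 tested, median log2 0.44, camera adjusted p = 0.0136; adjusted p = 0.991 with an estimated correlation). Dsx and Tra had differences of 0.13 ± 0.47 and 0.42 ± 0.36 (adjusted p = 1 and 0.92). DESeq2 gave 43 genes, voom 125, the fit without the least correlated libraries 10, log2(TPM + 1) with or without its filter 0, log2(TPM + 0.1) 2 and males alone 1, and leaving out B1A, B2A or B13 gave 3 (2 more positive, 1 more negative). The positive count was also 2 without B5D, B7, B8, B11, B14, B15 or B17, and the negative count 1 without B16 or B18 and 4 without B17 or B20.

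Sex in heads was compared at equal ploidy as 2N female minus 2N male. The P450 enzyme CYP9AG7 was at 11940 ± 4765 CPM in male heads and at 0.0662 ± 0.148 CPM in female heads (n = 5 each; log2 -17.43 ± 0.79, adjusted p = 1.17e-11), where the 6 counts of the latter were in B21. CYP6CK11 (log2 -10.73, and -11.60 without B25), CYP6CK8 (-8.91) and CYP4AB14 (-7.20) were lower in females too, while CYP4AB12 (3.76) and CYP4AB18, at 6.57 ± 4.52 against 0.0869 ± 0.0916 CPM, were higher. Tra was 7.92-fold higher in female heads, at 566 ± 29.9 against 71.4 ± 5.69 CPM (log2 2.99 ± 0.21, adjusted p = 7e-09), and Dsx 1.82-fold higher (log2 0.86 ± 0.16, adjusted p = 0.000681); the log2 difference of Fru was 0.45 (adjusted p = 0.137).

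Members of other lists differed by sex in heads as well. Odorant receptors, which detect volatile compounds in the antennae, rose in 13 of 95 in females and fell in 2, with Or276 (log2 2.84) and Or275 (2.28) higher and Or93 (-4.58) lower. The defensin LOC100121630 was higher in females (48.1 ± 7.77 against 8.45 ± 2.69 CPM, log2 2.52, adjusted p = 1.11e-06). Among 20 neuronal receptors and channels 3 were higher and 8 lower, with the acetylcholine receptor subunits nAChRb3 at log2 0.82 and nAChRa10 at -2.08. Akhr (log2 -1.68), Ecr (-0.81), the glutathione transferase GstT2 (-2.97), the cuticle genes CPR22 (-3.32) and CPR34 (-2.40) and the protease SP137 (-3.74) were lower in females, and GstS3 (1.41) was higher. LOC116416192 was at least 2880-fold higher (2177 counts against 0), LOC100122102 was at 8520 ± 2458 against 0.627 ± 0.517 CPM (log2 13.96), and LOC100123365 (log2 -12.66) and LOC100121233 (-3.76) were lower.

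By camera 5 of 20 lists differed between the sexes of 2N heads. These were sex determination (2 of 3 higher), cilia and dynein (4 of 10 higher, with Dctn4 at log2 0.49; each adjusted p = 0.0086), odorant receptors (0.0138) and mitochondrial ribosomal proteins (2 of 4 higher, with mRpL53 at log2 0.56; 0.0452) upward, and P450 enzymes (3 higher and 13 lower of 39; 0.0086) downward. With an estimated correlation these were adjusted p = 0.216, 0.216, 0.757, 0.569 and 0.569. Adjusted over the list alone, the higher members numbered 2, 7, 8 and 3, and P450 again had 3 higher and 13 lower. The germline gene oskar was higher in female heads (log2 3.04, adjusted p = 0.000576) and so was cyclin B, cycB (log2 4.83, adjusted p = 0.00631), with B21 at 101.5 and 42.27 CPM, far above the other heads; without B21 oskar passed with log2 1.65 (adjusted p = 0.000325) and cycB no longer passed (log2 0.95, adjusted p = 0.431).

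In total 1299 genes were higher and 1726 lower in 2N female heads, with 1983 higher and 1329 lower under library totals alone (a shift of the median of all genes by 0.126), and 1636 and 1257 on the log2(TPM + 1) scale. All 2N female heads are shallow and 1 of 5 2N male heads is, so no test within a depth class could be made; the count was 954 against a fold of 1.5 and 5660 with voom. Without B21 827 genes were higher.

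At the usual ploidy heads were compared as 2N female minus 1N male. Tra was at 566 ± 29.9 against 97.3 ± 39.1 CPM (n = 5 each; log2 2.54 ± 0.20, adjusted p = 6.38e-08), Dsx at log2 0.73 (0.0038) and Fru at log2 0.80 (0.015). CYP9AG7 (log2 -16.76, with its 6 counts in females in B21), CYP4AB14 (-6.81) and LOC100123365 (-11.48) were lower in females, and CYP4AB18 (7.03, and 8.11 without B1A) and LOC100122102 (11.95) were higher. The cuticle gene CPR48 reached 9080 ± 5545 CPM in 1N male heads and 130 ± 34.4 CPM in female heads (log2 -6.13, adjusted p = 0.00168). Akhr was lower (-2.20), and LOC100121630 was higher by log2 0.70 (adjusted p = 0.0466), a call lost without B2A, B3, B5D, B21, B22, B23, B24 or B25 (adjusted p = 0.0676 to 0.13).

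By camera, sex determination (3 of 3 higher, adjusted p = 0.00188), odorant receptors (6 of 95 higher and 2 lower, 0.00585) and cilia and dynein (3 of 10 higher, 0.025) lay higher in female heads than in 1N male heads. Cuticle (1 of 27 higher and 10 lower, 0.00182), P450 (2 of 39 higher and 14 lower, 0.00585) and the yellow family (5 of 14 lower, 0.0308) lay lower. These became adjusted p = 0.182, 0.763, 0.408, 0.408, 0.591 and 0.408 with an estimated correlation. Adjusted over the list alone, 3, 4 and 3 members were higher in the first group of lists, and 12, 14 and 6 lower in the second.

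In total 921 genes were higher and 1425 lower, with 1496 and 1128 under library totals alone (a shift of 0.109) and 1629 and 808 on the log2(TPM + 1) scale. Among shallow libraries, 5 against 4, 1313 passed, 1136 of them shared, against 540 for a fold of 1.5, 1443 with these groups alone, 1518 with all libraries in the fit and 4366 with voom. The higher count was 498 without B21 and 579 without B23.

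Sex in abdomens, 2N female minus 2N male, involved most genes. All 5 germline genes and 13 of 14 cell cycle genes were higher in females. The translational repressor nanos had 14457 counts in females and 0 in males, at least 12800-fold higher, and Kr was at least 4790-fold higher. Oskar was at 941 ± 68.3 against 1.295 ± 0.901 CPM (n = 4 and 5; log2 9.49 ± 0.58, adjusted p = 1.03e-10), cycB at 1489 ± 156 against 3.27 ± 2.28 CPM (log2 8.83) and Cdk1 at 428 ± 29.7 against 1.59 ± 0.386 CPM (log2 8.08). Of 15 DNA replication and repair genes 13 rose, and both methylation genes rose, Mbd (log2 2.90) and Dnmt1a (1.99).

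Members of other lists were lower in females. Of 42 P450 enzymes 37 were lower in females and 2 higher (median log2 -8.19), with CYP4AB14 at 0.392 ± 0.0985 against 1894 ± 198 CPM (log2 -12.20) and CYP6AQ4 at 1.69 ± 0.928 against 5202 ± 1033 CPM (log2 -11.59). CYP6CK8 had 1 count in females, in B28A, a ratio of 21500 (95% counting interval 3860 to 849000). Serine proteases were lower in 26 of 39 and higher in 3, with the homologue SPH103 at log2 -13.39 (-14.63 without B26A) and the protease SP37 at 12.37. Cuticle genes were lower in 24 of 30, with the chitinase Cht5 (-11.53) and CPR16 (-10.15), and neuronal genes in 16 of 19, with the sodium channel Para (-5.85). Akhr (-9.39), Def1-2 (-8.04) and Zasp66 (-6.66) were lower in females, and the glutathione transferase GstS8 (4.97) was higher. Dsx was lower in female abdomens, at 9.53 ± 1.56 against 388 ± 35.3 CPM (log2 -5.35 ± 0.59, adjusted p = 1.45e-07), while Tra and Fru had log2 differences of -0.02 and -0.18 (adjusted p = 0.95 and 0.471). Among genes without a descriptive symbol, LOC100123843 (log2 7.31) and LOC100119738 (4.42) were higher and LOC100119017 (-5.01) lower in females. LOC100379181 had 1 count in females, in B28A, and 94609 in males, a ratio of 35700 (95% counting interval 6400 to 1410000).

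By camera 11 of 20 lists differed: cell cycle (adjusted p = 4.91e-05), DNA replication and repair (0.000365), germline (0.0156) and mitochondrial ribosomal proteins (4 of 4 higher, 0.0324) upward, and P450 (8.14e-06), cuticle (0.00184), neuronal (0.00251), the transferases and carboxylesterases (23 of 29 lower, 4 higher) and the yellow family (12 of 15 lower; 0.00611 each), oxidative phosphorylation (43 of 65 lower, 3 higher, 0.0142) and proteases (0.0156) downward. With an estimated correlation 0 passed, with the lowest adjusted p = 0.0556 for cell cycle, 0.138 for DNA repair, 0.183 for germline, 0.342 for P450, cuticle, neuronal, mitochondrial ribosomal and yellow family genes, 0.408 for the transferases, 0.499 for proteases and 0.635 for oxidative phosphorylation. Adjusted over the list alone, 13 cell cycle, 13 DNA repair and 5 germline genes rose and 37 P450, 24 cuticle, 16 neuronal and 26 protease genes fell.

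At the usual ploidy 2N female abdomens were compared with those of 1N males. Nanos was higher by log2 10.77 (its 10 counts in 1N males were in B7), oskar by 8.74, Cdk1 by 7.88 and Dnmt1a by 1.92, and the cuticle gene CPR39, with 7686 counts against 0, was at least 3610-fold higher. CYP4AB14 (log2 -12.13), SPH103 (-13.40, and -14.63 without B26A) and Dsx (-5.40, adjusted p = 1.36e-07) were lower, and Tra had a log2 difference of -0.09 (adjusted p = 0.798). Cell cycle genes (13 of 14 higher, camera adjusted p = 2.58e-05) passed with an estimated correlation too (adjusted p = 0.0448). P450 enzymes were lower in 37 of 42 and higher in 2 (camera adjusted p = 1.08e-05, and 0.353 with an estimated correlation), and neuronal genes lower in 18 of 19 (0.00286 and 0.353). With p adjusted over the list alone, 13 cell cycle genes rose and 38 P450 and 18 neuronal genes fell.

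At equal ploidy 4422 genes were higher and 5497 lower in female abdomens, and at the usual ploidy 4356 and 5582; on the log2(TPM + 1) scale they were 5005 and 4331, and 5119 and 4302. The median log2 fold change of all genes was -0.46 and -0.51, which library totals alone shifted by 0.43 and 0.47 and median-of-ratios factors by -0.16 and -0.15, and depth classes left too few libraries for a test within a class in either comparison.

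Tissue was compared as abdomen minus head. In males CYP4G43, of the P450 subfamily that makes cuticular hydrocarbons, was at 8325 ± 2164 CPM in 1N and 12090 ± 5141 CPM in 2N male abdomens, against 24.5 ± 25.7 and 15.99 ± 16.5 CPM in heads (n = 5 each; log2 8.40 ± 1.01 and 9.56 ± 1.05, adjusted p = 6.98e-09 and 1.24e-09). SPH103 (log2 8.47 and 9.10) and SP50 (8.66 and 9.50) were also higher in abdomens. The long-wavelength opsin Lop1 was at 4226 ± 1923 and 3517 ± 1809 CPM in heads and at 0.683 ± 0.904 and 3.19 ± 1.60 CPM in abdomens (log2 -12.46 and -10.10). The histamine-gated channel HisCl1 was at least 1360-fold and at least 2810-fold lower in abdomens, the circadian neuropeptide Pdf lower by log2 -8.94 and -9.30, and CYP9AG7 by -10.96 and -9.95. Some of these folds moved with a single library. In 1N males, without B3, log2 was 9.23 for CYP4G43 and 9.48 for SP50, and without B10 it was -13.44 for Lop1, -10.04 for Pdf and -12.59 for CYP9AG7. In 2N males it was 10.31 for CYP4G43 without B13, -9.91 for Pdf without B18 and -10.70 for CYP9AG7 without B16.

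In male abdomens P450 enzymes were higher in 29 of 42 for 1N and 25 of 42 for 2N, lower in 7 and 8, the transferases and carboxylesterases higher in 21 of 29 and lower in 5 in each, and serine proteases higher in 20 and 21 of 40 and lower in 3 and 1. Cytosolic ribosomal proteins were higher in 4 of 4 in each. Neuronal genes were lower in 20 of 21 and higher in 1 in each, and odorant receptors lower in 65 and 73 of 143 and higher in 6 and 7. These lists passed camera in both kinds of males (adjusted p = 0.003 and 0.0115 for P450, 0.000947 and 0.00228 for the transferases, 0.0106 and 0.00915 for proteases, 0.0106 and 0.0115 for ribosomal proteins, 9.92e-06 and 3.38e-06 for neuronal genes, and 0.000947 and 7.13e-05 for odorant receptors). Under an estimated correlation the adjusted p was 0.41 and 0.326 for neuronal genes, 0.729 for the other lists in 1N males, and 0.668 in 2N males except P450 (0.736). Dsx was higher in male abdomens (log2 1.63 and 1.76, adjusted p = 8.06e-05 and 2.97e-05), and Tra (-1.41 and -0.99) and Fru (-1.13 and -1.38) were lower.

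In 1N males 3938 genes were higher and 4141 lower in abdomens, and in 2N males 4025 and 4071. Under library totals alone, which shifted the median of all genes by -0.35 and -0.34, they were 3066 and 5337, and 3066 and 5234, and on the log2(TPM + 1) scale 2451 and 6268, and 2459 and 6170. Among deep libraries, 5 abdomens against 4 heads of 2N males, 8089 genes passed, and in 1N males no depth class left enough libraries.

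In 2N females Cad (caudal) was at 40.1 ± 10.7 against 0.103 ± 0.146 CPM in heads (n = 4 and 5; log2 8.58 ± 1.03, adjusted p = 3.1e-09), Eve (even-skipped) at 34.6 ± 8.34 against 0.142 ± 0.116 CPM (log2 7.90), Hb (hunchback) at 30.5 ± 13.1 against 0.113 ± 0.153 CPM (log2 8.05) and nanos at 118 ± 29.97 against 0.361 ± 0.698 CPM (log2 8.36). CycB (log2 7.67), oskar (5.28), CPR39 (9.02) and Dnmt1a (3.16) were higher in abdomens too. The head values rest in part on B21, without which log2 was 11.52 for cycB, 11.11 for nanos, 9.69 for CPR39, 9.55 for Cad, 9.15 for Hb and 6.64 for oskar. In 3N females Cad was higher by log2 9.30, Hb by 10.93, nanos by 9.40, cycB by 10.49, oskar by 6.85 and Dnmt1a by 2.37. CPR39 had 6313 counts against 2, a ratio of 3600 (95% counting interval 996 to 29700). The head counts of Cad and nanos came from B33 alone and those of CPR39 from B32, and Hb was at log2 10.33 without B33 and 12.48 without B34A. The folds of 2N and 3N females therefore give no ploidy comparison for these genes.

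Lop1 had 0 counts in the abdomens of both kinds of females, at least 228000-fold lower than in heads in 2N and at least 246000-fold lower in 3N. The dopamine receptor Dop2 (at least 2020-fold) and the glutamate-gated channel GluCl (at least 890-fold) were lower in 2N abdomens, and HisCl1 (at least 1480-fold) and Pdf (log2 -11.93; -12.68 without B36A and -11.12 without B38) in 3N abdomens, where CYP4G43 was higher (log2 7.84). Dsx was lower in 2N female abdomens than in heads (10.9 ± 1.86 against 229 ± 43.2 CPM, log2 -4.39 ± 0.42, adjusted p = 1.41e-11) and at log2 -0.14 ± 0.33 in 3N females (adjusted p = 0.711). Tra was lower by log2 -3.93 and -2.34 and Fru by -1.95 and -2.46 in 2N and 3N abdomens.

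Neuronal genes were lower in abdomens in 20 of 21 and higher in 1 in both kinds of females (camera adjusted p = 1.17e-06 and 2.5e-08), and odorant receptors, adjusted over the list alone, lower in 110 and 112 of 143 and higher in 3 and 2 (0.000104 and 2.18e-07). Cell cycle genes were higher in 13 of 14 (6.42e-05 and 8.2e-05), DNA replication and repair genes in 14 of 15, with 1 lower in 2N (0.00022 and 0.000354), germline genes in 4 of 5 (0.0347 and 0.0489) and cytosolic ribosomal proteins in 4 of 4 (0.0487 and 0.0489). Oxidative phosphorylation genes were lower in 50 and 34 of 65 and higher in 2 and 3 (0.00048 and 0.0489). P450 enzymes were lower in 30 of 42 and higher in 7 in 2N females (0.00242), and lower in 16 and higher in 15 in 3N females (0.708), or 20 and 11 on the log2(TPM + 1) scale. With an estimated correlation the adjusted p was 0.104 and 0.118 for neuronal and for cell cycle genes, 0.104 and 0.123 for DNA repair, 0.348 and 0.378 for germline, 0.478 and 0.426 for odorant receptors, 0.478 and 0.51 for ribosomal proteins, 0.569 and 0.888 for oxidative phosphorylation and 0.508 for P450 in 2N females. Both odorant-binding proteins tested were lower in both.

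In 2N females 4674 genes were higher and 5287 lower in abdomens, and in 3N females 4745 and 4289, where the log2(TPM + 1) scale gave 3384 and 5325. Library totals shifted the median of all genes in 2N females by -0.10, and median-of-ratios factors by -0.28 there and -0.14 in 3N females. Among shallow libraries, 3 abdomens against 5 heads in 2N females and 4 against 2 in 3N females, 9644 and 6588 genes passed.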

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

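Chosen after the result was seen were the tests of the share of ovary RNA, of genes of other tissues, of cell cycle against ovary-enriched genes, of depth in female abdomens and for the genes of female heads, of the genes of male heads with a term for deep libraries, and of the identity of B39A. The tests of B21, of depth within 3N female heads for the genes of male heads and of other splits of the libraries were chosen before their results were seen.

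By camera 7 gene lists, among them P450 and cuticle genes, lay higher in 3N female abdomens and the cell cycle, DNA replication and repair and cilia lists lower, while the germline, muscle and hexamerin lists did not pass (adjusted p = 0.128, 0.506 and 0.21), and with an estimated correlation 0 of 20 lists passed. Deep libraries make up 1 of 4 of the 2N and 1 of 5 of the 3N abdomens. Depth is thus nearly balanced over ploidy, which argues against it as the whole cause. A term for deep libraries had little to remove, and 4476 of 4605 genes stayed past the threshold in the same direction with it. A shift of cell cycle genes below that of 526 ovary-enriched genes, of which 67 fell and 4 rose, was not seen. The medians were log2 -0.59 and -0.61 (quartiles of the latter -0.76 to -0.42). Of 10000 random lists of ovary-enriched genes, 60.4% lay at or below the cell cycle median. A small excess is not excluded, as 6 of the 14 members are among the 526. A lower share of ovary RNA in the 3N abdomens stays open: the main axis among the 3N libraries correlated at 0.86 across genes with the 3N minus 2N difference (at most 0.19 for the other abdomen groups), but B39A, beside the 2N libraries, sets that axis, and without B39A the value was 0.39 (at most 0.23). Other values do not settle it. With a term for the germline list, which itself did not pass, 4030 genes passed (3093 higher, 937 lower), 3616 of them shared. That term had the same slope for all abdomens. The list varied more within 1N males (mean log2 CPM -0.19 in B6A to 1.61) than within 3N females (5.93 to 6.76). The term could thus hardly remove a share of ovary RNA. Of 1771 genes over 16-fold lower in 2N female abdomens than in male abdomens and 2N female heads, 1445 rose and 1 fell. Genes so low in the 2N libraries could hardly fall. Among them the quartiles of log2 fold change overlapped for 23 P450 (5.21 to 6.24), 12 neuronal (3.73 to 5.43) and 14 cuticle genes (3.68 to 6.73). Those of 14 odorant receptors, of which 1 rose, lay below P450 (0 to 4.22). The whole odorant receptor list lay near the floor in all female abdomens (mean log2 CPM at most -2.217), so it tells little about an equal rise. A 2N abdomen under the label of B39A cannot be told apart from a 3N abdomen like the 2N ones. Its median correlation with 2N libraries (0.982) lay below their own lowest (0.985) by less than their range (to 0.991). Its rRNA share of 0.0262% lay with the other 3N libraries (0.0245 to 0.0434%) and above the 2N ones (0.00492 to 0.0103%). Its 9753 genes with at least 5 counts lay with the 2N libraries (9214 to 9952) and below the other 3N ones (10763 to 11487). Ploidy, ovary size, age and mating were not tested.

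In the 2N female head library B21 the germline list had a mean log2 CPM of 5.85 (4.65 to 4.97 in the other 4; gap over range 0.733), the cell cycle list 3.60 (2.26 to 2.52; 0.805) and oskar 101.5 CPM (8.70 to 16.9; 0.911). A candidate explanation is RNA of a female abdomen in that library: of the 100 most abundant abdomen genes over 16-fold lower in the other 4 female heads, 99 lay above the highest of those heads, against 18, 53, 14 and 15 when B22, B23, B24 and B25 were each set against the other 3. Those 4 heads took part in the choice of the genes and B21 did not, so the counts are not on equal terms. Their median was 31 CPM in B21, 5.93 in the other heads and 591 in abdomens, and the median excess was 2.54% of the abdomen level (quartiles 1.95 to 3.29%). The source of such RNA was not tested, and no biological explanation was tested, since the labels name no difference between B21 and the other heads.

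In heads 8 genes passed for ploidy in males and 34 in females, where deep libraries are unevenly spread over the ploidies. For the 34 genes the tables argue against depth as the whole cause, since 29 were among the 1913 that passed with shallow libraries alone and 34 among the 623 with a term for deep libraries, all in the same direction; the shallow 3N libraries, B34A and B35A, have letter names and the 2N ones none, so the former comparison is tied to the letter, with a term for which 154 passed, the 34 among them. For the 8 genes depth cannot be told apart from ploidy: within 3N female heads deep minus shallow, signed by the direction in males, had a median of 0.13 (quartiles -0.18 to 0.37), but that bound was drawn from females and does not reach depth effects in male heads. With a term for deep libraries all 8 kept their sign, their median absolute log2 change went from 2.02 (median standard error 0.32) to 1.57 (0.34), and the adjusted p from edgeR's test lay between 0.0622 and 0.209, so 0 passed; for 2 of the 8 the change was larger with the term, and the cause was not tested. Ploidy itself stays open for both sets of genes.

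Other splits of the same libraries into groups of the same sizes were counted to see whether chance can be excluded. For ploidy in male heads it cannot: 9 of 100 splits gave at least 8 genes, and the highest, 886, parted the 5 shallow from the 5 deep libraries, which points to a structure of the samples. Depth and a letter in the library name part the male heads in the same way, so either may underlie the 886. A value within either class could not be had there. For ploidy in male abdomens chance is not firmly excluded: 4 of 100 splits gave the 5 genes, the highest other was also 5, and 0 genes passed with male abdomens alone. In female heads it is excluded, with 34 genes in 1 of 100 splits and at most 4 in the others.

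For ploidy in female abdomens chance is not firmly excluded: 2 of 100 splits, the real one included, gave at least the 4605 genes. The highest other, 5892, set all 2N libraries and B39A against the other 3N libraries, which points to a structure of the samples in which B39A sits with the 2N abdomens. For ploidy by tissue in females chance is not firmly excluded either: 4 of 100 splits gave at least the 4012 genes, and the highest other, 5667, also placed B39A with the 2N abdomens. For ploidy by tissue in males it cannot be excluded (6 genes, 10 of 100 splits as large, highest other 15). For ploidy by sex in heads the count of 0 was met by 100 of 100 splits, so nothing is there to set against chance, and 1 split reached 202.

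For ploidy by sex in abdomens chance is not firmly excluded. The real split alone reached its 3217 genes, with 2956 as the highest other. Only 100 of 31752 possible splits were run, so this rests on which were drawn, and the count without B39A was 4338. Chance is excluded for sex at equal ploidy in heads (3025, highest other 85) and abdomens (9919, 6003) and at usual ploidy in heads (2346, 617) and abdomens (9938, 6724). The same holds for tissue in 1N males (8079, 4763), 2N males (8096, 3332), 2N females (9961, 8431) and 3N females (9034, 5090). In these 9 comparisons the real split alone reached its count. The highest of the other splits in each kept 4 libraries of a real group together.

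In direct tests the ploidy difference differed between the sexes in abdomens for 3217 genes and between the tissues in females for 4012. Between the tissues in males 6 genes passed, for which chance cannot be excluded.

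Single libraries far from their group were sought by the gap to the nearest other library divided by the range of the group, against Dixon's 95% critical value. Of 320 groups tested, 44 passed, where chance gives about 1 in 20. B39A held 9 of them, B21 7, B6A 6 and B12A 4.

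In the 3N female abdomen B39A the mean log2 CPM was lowest for muscle (6.10, others 7.41 to 7.91; ratio 0.721), oxidative phosphorylation (6.49, 7.14 to 7.33; 0.769), cytochrome P450 (0.10, 2.58 to 3.40; 0.753) and transferases and esterases (1.78, 3.57 to 4.22; 0.732). It was also lowest for serine proteases (-0.97, 1.44 to 2.32; 0.733) and immune genes (0.83, 2.52 to 3.02; 0.768). Tm2 (106.7 CPM, ratio 0.715), Bora (176.4, 0.725) and LOC100678734 (54.04, 0.854) were highest there, and E2f8 was highest in B38 (38.25, 0.865).

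In the 2N female abdomen B26A the lists of cilia (6.05, ratio 0.842), mitochondrial ribosomal proteins (7, 0.888) and serine proteases (-0.08, 0.835) were highest. In B30 immune genes were highest (0.73, 0.905), and sex determination (4.30, 0.966) and the first principal component of all libraries (-321.8, 0.845) lowest. For B21, beyond the lists above, transferases and esterases (4.43, 0.831), sex determination (7.76, 0.714), Dsx (163.9 CPM, 0.788) and the first component of all libraries (38.8, 0.85) were lowest. Among 3N female heads odorant receptors were lowest (-1.72, 0.766) and Kr highest (18.48 CPM, 0.738) in B35A, and in B34A oxidative phosphorylation was highest (8.04, 0.781) and sex determination lowest (8.10, 0.764).

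In the 1N male abdomen B6A the lists of germline (-0.19, ratio 0.861), cytosolic ribosomal proteins (8.86, 0.856), P450 (4.51, 0.753), transferases and esterases (4.43, 0.872), serine proteases (0.92, 0.932) and hormones (6.51, 0.851) were lowest. The first abdomen component was lowest in B8 (163, 0.766), LOC100107367 was above 0 in B9 alone (0.06 CPM, ratio 1), and Fru was lowest in the 2N male abdomen B17 (33.84, 0.752). In the 2N male head B12A gustatory receptors (-0.56, 0.774), cell cycle genes (1.91, 0.775) and P450 (4.21, 0.848) were lowest and muscle highest (8.05, 0.734). In the 1N male head B5D Tra (164.8, 0.769) and Dsx (202.5, 0.878) were highest and the second head component lowest (-102, 0.922), and Fru was lowest in B1A (36.06, 0.791).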

How the results depend on the processing

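The terms for deep libraries and for the germline list, the fits to shallow or deep libraries, the fit without B5D, B21, B6A and B39A, and the fit with library totals alone were chosen after data were seen; the other alternatives were chosen before the data were examined. No paired analysis was possible because the library numbers are unique and the labels do not tie a head to an abdomen.

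The counts for sex in abdomens and for tissue stayed within 1.5 times the reported count under every alternative run. They ranged from 8824 to 10538 and 8822 to 10418 genes for sex in abdomens at equal and usual ploidy. For tissue they ranged from 5867 to 9147 in 1N males, 5847 to 9427 in 2N males, 8778 to 10736 in 2N females and 6588 to 9338 in 3N females. For ploidy in female abdomens 13 of 16 alternatives stayed within 1.5 times. Of 4563 values of named genes under the alternatives, 4353 kept their side of the threshold, 186 kept the direction and no longer passed, and 24 newly passed. Where the gene passed in the main fit or the alternative, 0 values changed direction. Direction was not compared where it passed in neither. The rule chose most named genes for large or clear changes in these same data, so their direction could hardly change. Over all genes some calls did: for tissue in 1N males, 6414 of 6494 calls shared with log2(TPM + 1) kept their direction. Medians of some lists also changed sign on TPM scales. For ploidy by tissue in females the neuronal median went from log2 2.85 to -0.18 on log2(TPM + 1).

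Counts moved with the test. Against a fold of 1.5, counts were 3 for ploidy in male heads, 3 in male abdomens, 0 in female heads and 2723 in female abdomens, 954 and 540 for sex in heads at equal and usual ploidy, and 2409 for ploidy by tissue in females; a higher bar lowers counts by construction. DESeq2 gave 75, 71 and 562 for ploidy in male heads, male abdomens and female heads, 43 for ploidy by tissue in males and 13 for ploidy by sex in heads. Voom with sample weights gave 1036, 18, 1999 and 7588 for ploidy in male heads, male abdomens, female heads and female abdomens, 5660 and 4366 for sex in heads, 125 and 6613 for ploidy by tissue in males and females, and 622 and 5422 for ploidy by sex in heads and abdomens. On simulated counts for ploidy in female heads 32 of 163 DESeq2 calls were false, against 7 of 117 with voom and 7 of 119 with edgeR. In female abdomens these were 23 of 108, 15 of 81 and 2 of 57. False calls are thus 1 possible part of the higher counts of DESeq2 and, in female abdomens, of voom. For voom in heads the simulation gives no such sign. Its libraries shared the same spread for a gene, so it did not try the sample weights of voom. Beyond that the cause of the higher counts was not tested.

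The small counts also moved in fits on TPM and with the count filter or scaling. The TPM fits used limma-trend without TMM, so scale and test cannot be told apart there. Removing the TPM filter left male heads (13) and ploidy by tissue in males (0) unmoved. On log2(TPM + 1) there were 13 genes for ploidy in male heads, 1 in male abdomens and 0 for ploidy by tissue in males; on log2(TPM + 0.1), 1 in male abdomens and 2 for ploidy by tissue in males; without the TPM filter, 13 in male heads, 0 for ploidy by tissue in males and 3 for ploidy by sex in heads. Without the count filter there were 5 in male heads and 22 in female heads, and with library totals alone 72 in female heads. The cause was not tested.

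Terms and choices of libraries moved others. The letter term gave 0 in male heads, 154 in female heads and 1 for ploidy by sex in heads, and the term for deep libraries 0 in male heads and 623 in female heads. Shallow libraries alone gave 1913 in female heads, 2249 in female abdomens, 1313 for sex at usual ploidy in heads and 2073 for ploidy by tissue in females, and deep libraries alone 17 in male abdomens. With only the groups compared there were 0 in male heads, 0 in male abdomens, 1805 in female heads, 1443 for sex at usual ploidy in heads and 1 for ploidy by tissue in males. With all 39 libraries in 1 fit there were 1 in male heads, 30 in male abdomens, 74 in female heads and 1518 for sex at usual ploidy in heads. Without the least correlated libraries there were 17 in male heads, 10 in male abdomens, 10 and 6478 for ploidy by tissue in males and females, and 5021 for ploidy by sex in abdomens. Fits with fewer libraries have fewer degrees of freedom, which can lower a count, as for female abdomens with shallow libraries alone. This does not account for higher counts, such as 1805 and 1913 for ploidy in female heads, against 34 in the main fit. The cause of the higher counts was not tested.

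Leaving out 1 library at a time gave 3 to 63 genes for ploidy in male heads, 4 to 9 in male abdomens, 2 to 23 in female heads and 3492 to 5411 in female abdomens. For sex it gave 2360 to 2926 and 1586 to 2627 in heads and 9600 to 9810 and 9589 to 10047 in abdomens, at equal and usual ploidy. For tissue it gave 7795 to 8098, 7792 to 7930, 9633 to 9893 and 8787 to 9050 in 1N males, 2N males, 2N females and 3N females. Ploidy by tissue ranged from 3 to 9 in males and from 3350 to 5654 in females, and ploidy by sex from 0 to 1 in heads and from 2710 to 4338 in abdomens. In male heads each of B1A (3), B2A (3), B3 (63), B4A (4), B5D (19), B11 (3), B13 (5), B14 (3) and B15 (4) moved the count over 1.5 times, in male abdomens B6A (9), B8 (8) and B20 (8), for ploidy by tissue in males B1A, B2A and B13 (3 each), and for ploidy by sex in heads B3 (1). In female heads every library except B35A (23) did, with 2 without B23, B25, B31 or B32, 3 without B24, 5 without B22, 7 without B21, 9 without B34A and 17 without B33.

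Gene lists passed less often with an estimated correlation: 1 list passed, cell cycle for sex at usual ploidy in abdomens, over the 16 comparisons. By fry 17 of 20 lists passed in female abdomens, 1 in male heads, and 0 in female heads and male abdomens.

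Depth limits low genes, and depth classes are uneven over groups. A test within a class could not be made for ploidy in male heads, sex in heads at equal ploidy, sex in abdomens, tissue in 1N males, ploidy by tissue in males and ploidy by sex.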

Other observations

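Of the tests below, that of male against female heads was chosen before its result was seen, and its repeat with depth fitted in each sex was chosen after.

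Few genes passed for ploidy in heads of either sex, and a hypothesis was that both sexes share a ploidy response below the threshold. Across genes the 2N minus 1N difference in male heads correlated with the 3N minus 2N difference in female heads at 0.27 (one-sided permutation p = 0.0058 from 10000 shuffles of ploidy labels within each sex), and at 0.40 after a term for deep libraries, estimated with the real groups in the model, was removed (p = 0.011). A single term puts the same error into both differences and can raise the latter value. With the term fitted in each sex apart, and again in each of 99 shuffles, the correlation was 0.35 against at most 0.24 (p = 0.01, the smallest that these shuffles can give). Genes are not independent replicates, so the libraries were shuffled and not the genes. At an unadjusted p under 0.05 from edgeR's test, 477 genes were higher in males and 1147 in females, 137 of them in both, against 50.4 for independent lists. Lower were 682 and 841, 118 in both, against 52.9. LOC100121630 alone passed the adjusted threshold in both sexes, with log2 -1.82 in males and -1.36 in females. These values are consistent with a ploidy response shared by both sexes, but a difference in rearing, age or day between the ploidies that acted alike in both sexes was not tested, and depth is tied to ploidy in both.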
